A study of Chlorocebus sabaeus with 12 samples.

How the data were processed

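Gene expression was measured on 12 one-colour Agilent whole human genome arrays, on slides with 4 positions, in COS-1 cells, a kidney cell line from the African green monkey. The labels place 3 arrays in each of 4 groups: cells transfected with the S154A or the S154D mutant of human FXR for 24 h, then given 0.1% DMSO or chenodeoxycholic acid (CDCA, given in the labels as 50 mM) for 24 h. Nothing in the labels says that the replicates came from separate cultures, and the errors given are those between arrays. Monkey RNA was hybridised to human probes, and of the 20355 genes tested 10268 carry a name that is also a green monkey RefSeq symbol, so signal depends on how well each probe matches the monkey transcript.

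The deposited scanner files hold, for each of 45015 features, an intensity that Agilent Feature Extraction had background-subtracted and detrended within the array, along with flags per spot of 0 or 1. Per the file headers the software was version 9.5.3.1, whereas the submitters' notes name version 12, and the probe coordinates belong to the human genome build hg17. The deposited series table holds intensities on a linear scale, and all 45015 of its values equalled the processed signal of the scanner files, to within rounding, on each of the 12 arrays, so the authors had applied no normalisation between arrays, and its column medians ranged from 104.56 to 214.28.

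The processed signal was put on the log2 scale, and the 75th percentile of the array's non-control spots was subtracted, so that a value of 0 is the level of that percentile. Spots marked as outliers by the software, 66 to 196 per array, were removed, and the 43376 non-control spots were averaged into 41000 probes with 30982 names. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 26898, and the brightest kept probe stood for each gene name, which left 20355 genes, 12671 of them with a gene symbol. For 5072 of the genes tested more than 1 probe was kept, and 113 lacked a value on 1 or more arrays. Across arrays, 61.6% to 79.8% of spots were well above background, the 75th percentile lay between 1234 and 2107, and 0 to 3 spots were saturated. With 3 arrays per group, the number of arrays limits the precision.

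One mean per group was fitted to all 12 arrays with limma (version 3.58.1, in R 4.3.3, with version 1.17.8 of the package data.table), with moderated variances (prior degrees of freedom 2.3, residual 8), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested within a comparison. A gene was called changed, higher or lower at an adjusted p under 0.05. All tests were two-sided. The comparisons were CDCA against DMSO with each mutant, S154D against S154A with each treatment, and the difference between the responses to CDCA, S154D minus S154A. Errors of log2 changes are the standard errors of the fit, with 3 arrays in each group, and intervals are at 95%. Where no array of the dimmer group was well above background, its values were raised to the dimmest probe well above background on the same array, and the fold against that level is printed as "at least". The correlation of both responses was computed across genes, which are not independent replicates, so it carries no p-value.

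The comparisons, the filter, the threshold, the rule for naming genes and 24 gene lists were fixed before the data were examined. For each pairwise comparison the rule named, among called genes with a gene symbol and no overlap between the arrays of both groups, the 12 with the largest rise and the 12 with the largest fall, or the 10 with the smallest p where fewer than 10 passed. For the difference between the responses it named the 5 largest each way, and in every comparison NR1H4, the gene of FXR, and the FXR targets OSTalpha, OSTbeta, FGF19, NR0B2, ABCB11 and CYP7A1, with up to 4 members of each list described. Some genes that the rule names are not reported here. The lists held FXR targets, bile acid synthesis and transport, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation, the unfolded protein and integrated stress response, the NRF2 response, heat shock proteins, immediate early and ERK pathway genes, NF-kB and inflammatory genes, interferon-stimulated genes, cell cycle genes, p53 targets, proteasome subunits, xenobiotic metabolism, hypoxia and glycolysis, extracellular matrix and TGF-beta targets, nuclear receptors and coregulators, ribosomal proteins, the mitochondrial respiratory chain, housekeeping genes, and markers of hepatocytes, leukocytes and epithelial cells. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members of a list move at all, adjusted over the 24 lists.

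The names of the scanner files place the arrays on 4 slides. Slide 3 held all 4 groups, slide 2 held S154A_DMSO 2 and both S154D_CDCA 1 and 3, and slide 4, scanned on another day than the rest, held S154A_CDCA 2 and S154D_DMSO 2. The 3 S154A_DMSO arrays were all at position 1 of their slides, which no other group used. Alternatives fixed with the design were quantile normalisation, normexp background correction (offset 50) with quantile normalisation, the deposited series table, no filter, only probes well above background on all 12 arrays, the mean of a gene's probes, slide as a fixed or a random block, replicate number as a block, a variance trend with robust moderation, a minimum of 1.5-fold, only the 6 arrays compared, and each array left out in turn. Chosen after seeing the data were a correction for probe GC content (a natural spline with 4 degrees of freedom per array), fits without slide 2 or slide 4, and array position as a block, fitted without the S154A_DMSO arrays. The lists were not tested with slide as a random block. A first look at the counts, lists and GC correlations under several of these settings preceded the account below, and the settings fixed in the design were kept as the ones reported.

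On simulated data with 200 changed genes among 20355 and the spread of these arrays, 53.7% to 68.7% of changes of 1 log2 unit were called in the pairwise comparisons and 29.9% in the difference between the responses, with 4 to 8 false calls. At 0.5 log2 units 5.97% to 11.9% were called in the pairwise comparisons, at 2 log2 units 84.8% to 90.9%, and with no simulated change no gene was called. The simulated noise was independent between genes and arrays, without slide or GC differences, so these false calls hold only for such noise. With a GC trend of preset size added to the S154D_CDCA arrays, 2955 unchanged genes were called for CDCA in S154D cells, and 10 after the GC correction.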

Results

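The series asked what phosphorylation means for FXR (NR1H4), the nuclear receptor that senses bile acids. In the mutants S154A and S154D a serine of FXR was replaced by alanine, which cannot be phosphorylated, or by aspartate, whose charge resembles that of a phosphate. COS-1 cells carrying either mutant were compared with and without CDCA, a bile acid that activates FXR, on 3 arrays for each of the 4 groups. No array held cells with wild-type FXR or without transfected FXR. The NR1H4 probe, at 99459659 to 99459718 on chromosome 12 in hg17, was well above background on all 12 arrays, at 7.74 ± 0.16 in S154A_DMSO, 7.59 ± 0.13 in S154A_CDCA, 7.77 ± 0.27 in S154D_DMSO and 7.56 ± 0.13 in S154D_CDCA (log2 above the 75th percentile of the array, mean ± SD, n = 3). These levels did not differ between S154D and S154A in CDCA (log2 difference -0.03, 95% interval -0.36 to 0.30, adjusted p = 0.916) or in DMSO (0.03, adjusted p = 0.999).

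The first comparison asked which transcripts CDCA changed in S154A cells. The largest rises were those of 2 FXR targets, FABP6 and FGF19. FABP6, the ileal bile acid-binding protein, rose by 7.08 ± 0.57 log2 units, or 135-fold (adjusted p = 0.000621), from -4.56 ± 0.96 to 2.52 ± 0.07 (mean ± SD, n = 3). FGF19, a hormone that lowers bile acid synthesis in the liver, was well above background on 0 of 3 DMSO arrays and on 3 of 3 CDCA arrays, and was at least 23.9-fold higher with CDCA (fitted log2 change 6.03 ± 0.76, adjusted p = 0.012). OSTalpha, a subunit of the exporter that carries bile acids out of cells, rose by 2.55 ± 0.18 log2 units, or 5.88-fold (adjusted p = 0.000245). Its partner OSTbeta, near background in DMSO with 1 of 3 arrays well above it, had a log2 change of 1.70 ± 0.69 and was not called (adjusted p = 0.82), with 0.14 within slide 1, 2.11 within slide 3 and 1.28 with slide as a block.

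Of the 24 FXR targets tested, 5 rose and 0 fell, and the same number passed when adjusted over the list alone. Besides FABP6, FGF19 and OSTalpha these were FETUB, the plasma protein fetuin-B (1.71 ± 0.17), and SDC1, the heparan sulfate proteoglycan syndecan-1 (1.14 ± 0.12). The median change of the list was 0.04 and the mean 0.79, so the shift lay in few members (camera adjusted p = 1.81e-06, and adjusted p = 0.174 with an estimated correlation). By fry the members changed in either direction (adjusted p = 1.47e-08), and a move one way on balance did not pass (adjusted p = 0.054). The mean change of the list was 0.56 within slide 1, 1.04 within slide 3 and 0.79 with slide as a block. NR0B2, ABCB11 and CYP7A1, which encode a corepressor, the bile salt export pump and the first enzyme of bile acid synthesis, were well above background on at most 2, 1 and 0 arrays and were not tested.

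In all, 27 of 20355 genes were called by limma, 26 higher and 1 lower, and 1230 had an unadjusted p under 0.05. Other symbols among the largest rises were HRG, a plasma glycoprotein (3.24 ± 0.34, with 1 of 3 DMSO arrays well above background), RBP4, the carrier of retinol in blood (2.21 ± 0.15), MYOM2, a protein of the sarcomere (1.81 ± 0.15), BAIAP2L2 (1.42 ± 0.10), SAMD11 (1.22 ± 0.14) and MEGF6 (1.22 ± 0.18). CCDC37 was well above background on 0 of 3 DMSO arrays and was at least 2.08-fold higher with CDCA. The only lower one, AW015664, is a transcript without a symbol that was named after its values were seen. It was well above background on 3 of 3 DMSO and 0 of 3 CDCA arrays, and was at least 2.81-fold lower with CDCA (fitted log2 change -2.75).

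Members of the unfolded protein and integrated stress response lay higher together in S154A cells, although none was called. Of 29 tested, 25 had a positive change, with a median of 0.16 (camera adjusted p = 1.81e-06, and adjusted p = 0.174 with an estimated correlation). Its largest changes were NUPR1 at 2.12 ± 1.22, PHGDH, an enzyme of serine synthesis, at 0.46 ± 0.17, and DDIT3, the stress-induced factor CHOP, at 0.43 ± 0.18, with 0 called when adjusted over the list alone. The mean change of this list was 0.20 within slide 1, 0.35 within slide 3 and 0.22 with slide as a block. The list also lay above S154A_DMSO in S154D_DMSO (mean 0.17), and with CDCA the mean difference between the mutants was -0.04 (camera adjusted p = 0.454). A low level on the S154A_DMSO arrays, all at position 1, cannot be told apart here from a change with CDCA. Fatty acid synthesis genes (median 0.09 over 17, adjusted p = 0.0456, and adjusted p = 0.174 with an estimated correlation) and epithelial markers (median 0.14 over 10, adjusted p = 0.0455, and adjusted p = 0.208 with an estimated correlation) also passed, with 0 members called. In the other 20 lists 0 members were called over all genes, and no list passed, at adjusted p from 0.276 to 0.955.

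All 27 genes kept their direction within slide 1 and within slide 3, although they had been selected on these same arrays. With slide as a block 7 were called, namely FABP6 (6.91 ± 0.70, adjusted p = 0.0498, in a range over all alternatives from 3.17e-08 to 0.0498), OSTalpha (2.61 ± 0.19, adjusted p = 0.0185, range 2.27e-05 to 0.0185), RBP4, MYOM2, HRG, BAIAP2L2 and the unnamed probe A_32_P232437, whereas FGF19 was not (6.26 ± 0.78, adjusted p = 0.0951). Leaving out 1 array gave 14 genes without S154A_DMSO 1, S154A_DMSO 3, S154A_CDCA 1 or S154A_CDCA 2, 15 without S154A_CDCA 3 and 17 without S154A_DMSO 2, and 9 were called without slide 2 and 14 without slide 4. The call of FGF19 was lost without S154A_DMSO 2 (adjusted p = 0.0802), S154A_DMSO 3 (0.0763), S154A_CDCA 1 (0.073), S154A_CDCA 2 (0.0664) or S154A_CDCA 3 (0.089), in a range over all alternatives from 9.81e-06 to 0.124. Each single omission also ended the calls of CCDC37 (adjusted p from 0.0676 to 0.193) and MEGF6 (0.0614 to 0.213), and SAMD11 was lost without S154A_DMSO 1, S154A_DMSO 3 or S154A_CDCA 1 (at most 0.0547). OSTalpha, RBP4 and MYOM2 were called under every alternative run. FABP6 was called under every alternative that tested it. It was left out where only probes well above background on every array were kept.

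**Figure D1:**
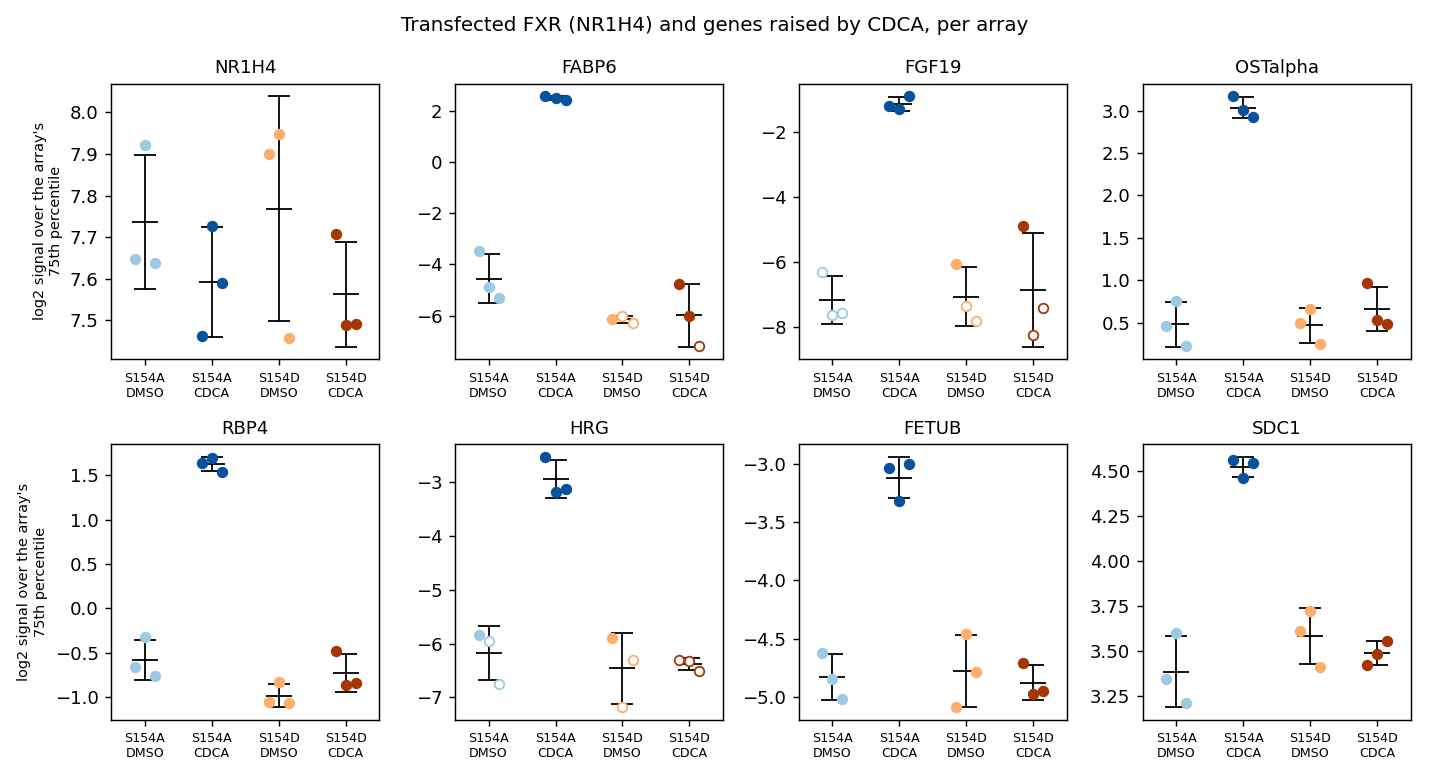
Level of selected genes on each of the 12 arrays, by group, in log2 units above the array's 75th percentile, with a separate vertical axis for each panel. Filled points were well above background and open points were not, and bars are the mean ± SD of 3 arrays; FABP6, FGF19 and OSTalpha stand highest in S154A_CDCA.

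The second comparison asked the same of S154D cells. The FXR targets that rose in S154A cells were not called: the log2 change was 0.16 ± 0.57 for FABP6 (adjusted p = 0.879), 0.20 ± 0.76 for FGF19 (adjusted p = 0.886), 0.19 ± 0.18 for OSTalpha (adjusted p = 0.494), -0.10 ± 0.17 for FETUB (adjusted p = 0.739) and -0.10 ± 0.12 for SDC1 (adjusted p = 0.634). The 95% intervals reached 1.42 for FABP6 and 1.90 for FGF19. On S154D_CDCA 1, FABP6, FGF19 and OSTalpha lay above every S154D_DMSO array, whereas FETUB and SDC1 did not. None of them did so on S154D_CDCA 2 or 3. FGF19 had -1.37 on its other probe, and the probe used was well above background on 1 of 3 S154D_DMSO and 1 of 3 S154D_CDCA arrays. OSTbeta, not called in S154A cells, had 0.03 ± 0.69 (adjusted p = 0.984). Of the 24 FXR targets tested, 0 were called over all genes and 0 when adjusted over the list alone, with a median change of 0.07 (camera adjusted p = 0.919). Within slide 3 the change was 0.28 for OSTalpha. The 26 genes raised in S154A cells had a median change of -0.04 here, against 1.22 there. Both changes come from separate arrays, but the filter, the choice of probe and the spread behind the calls used all 12 arrays. The set is therefore not independent of the S154D arrays, and with only the 6 S154A arrays 11 of the 27 called genes were still called. In S154D cells the 26 genes ranged from -0.63 to 0.60, and 12 of them were positive (camera p = 0.311, and p = 0.609 with an estimated correlation). The 2 that were called, the unnamed probes A_24_P178444 (-0.42) and A_24_P306814 (-0.49), were lower with CDCA. The upper 95% bound lay below the S154A estimate for 26 of 26. These genes had been selected for a large S154A estimate, whose error this leaves out. The test of the difference between the responses called 16 of the 26.

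CDCA was instead accompanied by many small differences in S154D cells. ALDH3A1, an aldehyde dehydrogenase, was at least 3.06-fold higher, with 0 of 3 DMSO arrays well above background. GATM, an enzyme of creatine synthesis, was higher by 1.66 ± 0.21 log2 units (1.18 after a correction for probe GC), SENP6, a SUMO protease, by 1.43 ± 0.18 (0.68 on its other probe, and 0.67 after that correction) and PPA2, a mitochondrial pyrophosphatase, by 1.31 ± 0.21 (1.01 after it). Lower were HFE, a regulator of iron uptake (-1.78 ± 0.50, and -1.55 and -0.57 on its other probes), the kinase AKT1 (-1.19 ± 0.31), EDC4, a scaffold of mRNA decapping (-1.12 ± 0.24), and SEC24C, a coat protein of vesicles leaving the endoplasmic reticulum (-1.11 ± 0.23). The other rises named by the rule, CLEC1B, IGHM, ZNF354C, WWC2, ZNF509, TPH1, ZNF181 and ARRDC4, lay between 1.33 and 2.00, of which CLEC1B, ZNF354C and TPH1 had 0 of 3 DMSO arrays well above background and were at least 1.65-fold, 2.69-fold and 1.4-fold higher. The other falls, OR10A5, SLC26A1, DPYSL5, STH, LRCH3, NBEAL2 and MAP1LC3C, lay between -1.79 and -1.10; STH was well above background on 0 of 3 CDCA arrays and was at least 2.09-fold lower, and the other 3 probes of SLC26A1 gave 0.33, 0.06 and -0.34.

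In all, limma called 2073 genes, 1312 higher and 761 lower, of which 141 changed at least 2-fold. Their median absolute log2 change was 0.62, the smallest adjusted p was 0.0271, and 6102 genes had an unadjusted p under 0.05. The changes followed the GC content of the probes across genes (Spearman -0.56 over 20355 genes, which are not independent replicates), against -0.11 for CDCA in S154A cells. It was 0.31 for S154D against S154A in DMSO, -0.39 in CDCA and -0.40 for the difference between the responses. Each of these uses S154D arrays that this comparison also uses, so they do not show the trend apart from it. The median probe GC was 35% among genes called higher and 55% among those called lower, against 45% over all genes. After a correction for probe GC, chosen after seeing the data, 0 genes were called by limma and 3786 had an unadjusted p under 0.05. Of the 2073 genes 1324 still had an unadjusted p under 0.05, and their median absolute log2 change went from 0.62 to 0.38 with a median standard error of 0.141 before and 0.144 after.

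With slide as a block 0 of these genes were called by limma and 4508 had an unadjusted p under 0.05, while all 2073 kept their direction within slide 3, the 1 slide holding both groups and a source of the selection itself. The count was 1 without S154D_DMSO 1, 0 without S154D_DMSO 3 or S154D_CDCA 3 (4469 and 4365 at an unadjusted p under 0.05), 722 without S154D_CDCA 2 and 6 without slide 2, and 0 to 2679 over all alternatives. No list passed by camera (smallest adjusted p = 0.143), and by fry none moved one way on balance (smallest adjusted p = 0.255). Members of many lists did change in either direction by fry, such as xenobiotic metabolism (adjusted p = 2.49e-05) and heat shock proteins (9.36e-05). Those of the FXR targets did not (0.339). Fry does not set a list against the other genes, and by limma 6102 of all 20355 genes had an unadjusted p under 0.05. Passing it is therefore no mark of the lists named. Fry was not run after the GC correction or with slide as a block. Across genes the responses of S154D and S154A cells had a Pearson correlation of -0.10 and a Spearman correlation of -0.12. With 1 array left out, the Pearson value ran from -0.20 without S154D_CDCA 3 to 0.08 without S154D_CDCA 1, so its sign depends on 1 array.

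**Figure D2:**
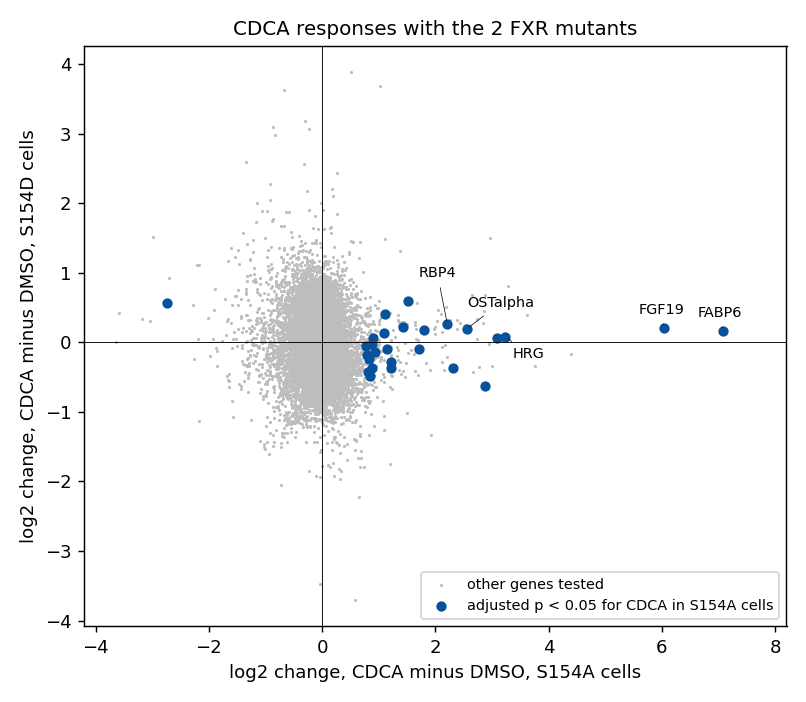
Log2 change with CDCA in S154A cells (horizontal) against that in S154D cells (vertical) for 20355 genes, with the 27 genes called in S154A cells in blue. The 26 genes raised in S154A cells had a median of 1.22 along the horizontal axis and -0.04 along the vertical one.

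**Figure D3:**
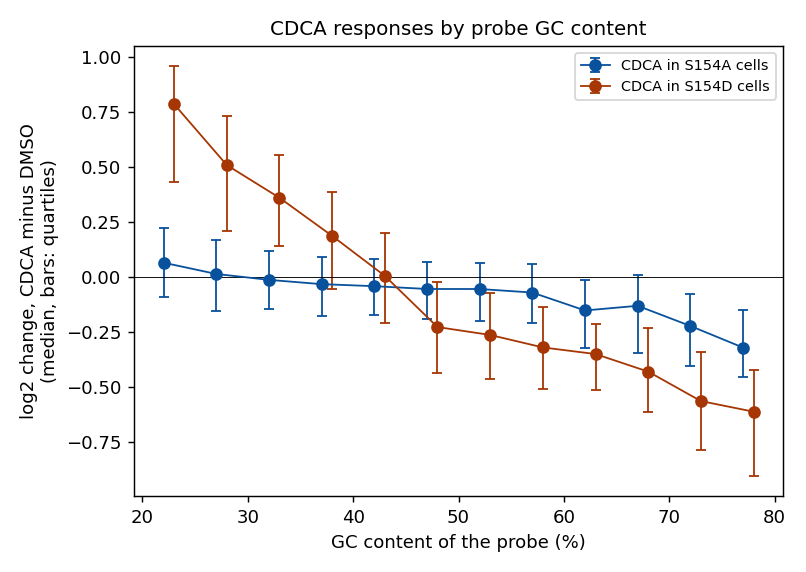
Median log2 change with CDCA by GC content of the probe (%), in S154A cells (blue) and S154D cells (orange-brown), with bars from the lower to the upper quartile of genes. Values decline with GC in both, with a Spearman correlation of -0.56 in S154D and -0.11 in S154A cells.

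The third comparison asked whether the mutants differed without CDCA. No FXR target was called: the log2 difference, S154D minus S154A, was -0.02 ± 0.18 for OSTalpha (adjusted p = 0.999), -0.29 ± 0.69 for OSTbeta and 0.11 ± 0.76 for FGF19, the last 2 near background in both groups. FABP6, well above background on 1 of 3 S154D_DMSO and 3 of 3 S154A_DMSO arrays, had a difference of -1.59 ± 0.57 (95% interval -2.85 to -0.33, unadjusted p = 0.0183, adjusted p = 0.996), at -2.68 within slide 1 and -0.98 within slide 3. FXR targets as a list had 0 called members, also when adjusted over the list alone, and a median of 0.00 (camera adjusted p = 0.947). Limma called 0 of 20355 genes, 884 had an unadjusted p under 0.05, and the smallest adjusted p was 0.996. Among the 10 genes with the smallest p, 9 were lower in S154D cells, such as FBXO5, an inhibitor of the anaphase-promoting complex (-0.67 ± 0.16), HMG4L (-0.54 ± 0.12), NCBP1, a subunit of the mRNA cap-binding complex (-0.40 ± 0.10), MTO1, TPH1, TMOD2, ASCC3L1, ZNF702 and ZNF491, and PPP1R3D was higher (0.57 ± 0.14). ZNF491, well above background on 0 of 3 S154D_DMSO arrays, was at least 2.06-fold lower, but at adjusted p = 0.996 none of the 10 passed the test.

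Ribosomal protein genes lay slightly higher in S154D cells in DMSO, with 37 of 40 positive, a median difference of 0.16 and 0 called (camera adjusted p = 6.64e-08, and adjusted p = 0.885 with an estimated correlation). RPS6 (0.32 ± 0.11) and RPS14 (0.27 ± 0.12) were the largest. The mean of the list, 0.14 here, was 0.15 within slide 1, 0.11 within slide 3 and 0.12 with slide as a block, and turned to -0.01 with quantile normalisation and -0.02 with normexp, where the list was not called (adjusted p = 0.971 and 0.958, in a range over all alternatives from 1.46e-13). Without slide 4 the call was also lost (adjusted p = 0.0514), and on the series table the mean was -0.10 beside a median of -0.24 over all genes. The unfolded protein and integrated stress response lay higher too, with 23 of 29 positive and a median of 0.14 (adjusted p = 0.0237, and adjusted p = 0.682 with an estimated correlation), at a mean of 0.25 within slide 1, 0.18 within slide 3 and 0.15 with slide as a block, where its call was lost (adjusted p over all alternatives from 0.000382 to 0.392). It was also lost without S154A_DMSO 1 (0.132) or S154D_DMSO 1 (0.392). This shift and the one with CDCA in S154A cells are both measured against the S154A_DMSO arrays, so they are not separate observations. No other list passed.

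The fourth comparison asked whether the mutants differed in the presence of CDCA. Of 24 FXR targets tested 5 were lower in S154D cells. For FABP6 the log2 difference, S154D minus S154A, was -8.51 ± 0.57 (adjusted p = 0.000194), with 2 of 3 S154D_CDCA arrays and 3 of 3 S154A_CDCA arrays well above background. The difference was -5.72 ± 0.76 for FGF19 (adjusted p = 0.0123), with 1 of 3 S154D_CDCA arrays well above background, -2.38 ± 0.18 for OSTalpha (adjusted p = 0.000291) and -1.96 ± 0.69 for OSTbeta, which was not called (adjusted p = 0.139) and had -1.06 with slide as a block. None was higher, and the same number were lower when adjusted over the list alone, with 11 of 24 positive, a median of -0.02 and a mean of -0.81 (camera adjusted p = 0.0191, and adjusted p = 0.938 with an estimated correlation). By fry the list lay lower on balance (adjusted p = 0.0426), and its members differed in either direction (adjusted p = 8.17e-08). The mean was -0.97 within slide 3 and -0.79 with slide as a block. The camera call was lost without S154A_CDCA 1 (adjusted p = 0.0532) or S154D_CDCA 2 (0.0592), in a range over all alternatives from 7.26e-05 to 0.268.

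Limma called 82 genes, 15 higher and 67 lower in S154D cells, and 4802 had an unadjusted p under 0.05. Also lower were RBP4 (-2.36 ± 0.15), MYOM2 (-2.14 ± 0.15), FETUB (-1.76 ± 0.17), SAMD11 (-1.63 ± 0.14), WDFY4 (-1.53 ± 0.23) and MEGF6 (-1.47 ± 0.18). HRG and CCDC37, with 0 of 3 S154D_CDCA arrays well above background, were at least 9.66-fold and 2.92-fold lower. DLX3, a homeobox factor, was lower on the probe used (-1.73 ± 0.18, with 1 of 3 S154D_CDCA arrays well above background) and had 0.67 on its other probe. The rises with a symbol named by the rule were CAMK2N2, an inhibitor of a calcium-dependent kinase (1.83 ± 0.32), the receptor kinase FLT3 (1.20 ± 0.21), MRPL44, a protein of the mitochondrial ribosome (0.93 ± 0.13), the Fc receptor FCGR3A (0.90 ± 0.12) and TAF1A, a factor of ribosomal RNA transcription (0.67 ± 0.11).

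All 82 genes kept their direction within slide 3, although its arrays were among those on which they had been selected. There FABP6 differed by -8.60 and OSTalpha by -2.64, with 1 array per group, and FGF19 was not well above background on the S154D_CDCA array. With slide as a block 3 were called, RBP4 (-2.50 ± 0.16, adjusted p = 0.0145), MYOM2 and OSTalpha (both adjusted p = 0.0483), while FABP6 (-8.11 ± 0.82) and FGF19 (-5.85 ± 0.92) were not (adjusted p = 0.0513 and 0.181). With array position as a block 0 were called by limma, 3120 had an unadjusted p under 0.05, and the adjusted p was 0.0683 for FABP6, 0.0827 for RBP4 and 0.0841 for OSTalpha, the largest of their alternatives, which began at 1.21e-08, 1.11e-05 and 5.23e-05. The count was 19 without S154A_CDCA 3, 25 without S154D_CDCA 3, 34 without S154D_CDCA 2 and 285 without S154D_CDCA 1, and 18 without slide 2. The share of higher genes was 18.3%, and 39.3% of 196 genes with quantile normalisation and 38.1% of 197 with normexp. FGF19 was lost without S154A_CDCA 3 (adjusted p = 0.0814) or S154D_CDCA 3 (0.0765), in a range over all alternatives from 1.11e-05 to 0.257, and MEGF6 without S154A_CDCA 3 (0.0562). CAMK2N2 was lost on every single omission (adjusted p from 0.0541), and FLT3, MRPL44, TAF1A and WDFY4 on 5 of 6 and FCGR3A on 3 of 6 (at most 0.206, 0.0801, 0.196, 0.131 and 0.0645).

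The last comparison tested whether the response to CDCA itself differed between the mutants. It did for FABP6, with a difference between the responses, S154D minus S154A, of -6.92 ± 0.80 (adjusted p = 0.0209), for OSTalpha (-2.36 ± 0.25, adjusted p = 0.0209), for RBP4 (-1.95 ± 0.21, adjusted p = 0.0209) and for HRG (-3.16 ± 0.47, adjusted p = 0.0462). The values of HRG and FABP6 depend on signal near background: HRG was well above it on 1 of 3 arrays of S154A_DMSO and of S154D_DMSO and 0 of 3 of S154D_CDCA, and FABP6 on 1 of 3 of S154D_DMSO and 2 of 3 of S154D_CDCA. FGF19 did not pass (-5.83 ± 1.08, adjusted p = 0.0623, and -7.54 on its other probe), and its value too depends on signal near background, with 0 of 3 S154A_DMSO, 1 of 3 S154D_DMSO and 1 of 3 S154D_CDCA arrays well above it. OSTbeta did not pass either (-1.67 ± 0.98, adjusted p = 0.338, and -0.36 with slide as a block). Of 24 FXR targets 4 were called lower over all genes and 5 when adjusted over the list alone, with a median of -0.09 and a mean of -0.73, and the list did not pass by camera (adjusted p = 0.0872, and adjusted p = 0.847 with an estimated correlation). By fry the members differed in either direction (adjusted p = 1.37e-07), and a move one way on balance did not pass (adjusted p = 0.316). The mean of the list was -0.94 within slide 3 and -0.70 with slide as a block. The difference was also called for FBXO5 (1.57 ± 0.23), HMG4L (1.21 ± 0.17) and NCBP1 (0.91 ± 0.14), which had positive changes in S154D and negative ones in S154A cells. DLX3 went the other way on the probe used (-1.89 ± 0.25), with 0.87 in S154A and -1.03 in S154D cells, near background (1 of 3 S154A_DMSO and 1 of 3 S154D_CDCA arrays well above it), and its other probe gave 1.16. After the GC correction the calls of FBXO5 (1.25, adjusted p = 0.11), HMG4L (1.17, 0.0517) and NCBP1 (0.59, 0.193) were lost, and those of FABP6, OSTalpha, RBP4, HRG and DLX3 were not.

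In all 30 genes were called, 9 with a higher and 21 with a lower response in S154D cells, and 4560 had an unadjusted p under 0.05. With slide as a block 0 were called by limma and 3065 had an unadjusted p under 0.05, with an adjusted p of 0.297 for FABP6 (-6.35 ± 1.21), OSTalpha (-2.56 ± 0.33) and RBP4 (-2.14 ± 0.24). Over all alternatives it ran from 1.75e-06 to 0.297 for FABP6, 0.00183 to 0.297 for OSTalpha and 0.00231 to 0.319 for RBP4. Within slide 3, with 1 array per group, the difference was -2.67 for OSTalpha and -2.20 for RBP4. The count was 0 without S154A_DMSO 3, S154A_CDCA 2, S154A_CDCA 3, S154D_DMSO 1, S154D_CDCA 2 or S154D_CDCA 3, 1 without S154A_DMSO 1, 2 without S154A_DMSO 2, 4 without S154D_DMSO 3, 6 without S154D_DMSO 2, 14 without S154D_CDCA 1 and 67 without S154A_CDCA 1. Where it was 0, between 3183 and 4801 genes had an unadjusted p under 0.05 by limma. The call was lost on 7 of 12 omissions for OSTalpha and RBP4 (adjusted p at most 0.0842), 9 of 12 for FABP6 (at most 0.102), and 11 of 12 for HRG, DLX3, FBXO5, HMG4L and NCBP1 (at most 0.155). The share of higher genes was 30%, and 62.7% of 118 genes with quantile normalisation and 60.4% of 197 with normexp.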

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

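The tests of the NR1H4 level, of the slide block on FXR targets and of wrong labels were chosen only after the results they measure had been seen. A difference between the mutants in the response to CDCA, tested as such, singled out 30 genes, among them FABP6 (-6.92), HRG (-3.16), OSTalpha (-2.36) and RBP4 (-1.95), called with CDCA in S154A and not in S154D cells, and DLX3 (-1.89, but 1.16 on its other probe), FBXO5 (1.57), HMG4L (1.21) and NCBP1 (0.91), whose changes had opposite signs in the mutants (log2, S154D minus S154A). Of 100 draws of the 12 arrays into 4 groups of 3, the real one included, 3 gave as many genes or more. The highest other draw gave 1968, far above the real count, while 90 of the 99 other draws gave none by limma. A draw can mix the real groups, so it cannot tell whether a structure apart from the groups lies behind its count. The arrays' trend with probe GC, contrasted over the groups of that draw, was 0.1037. The median absolute contrast of the draws was 0.2911, and the real grouping had -0.6634, so that draw did not stand out by GC.

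FXR targets raised by CDCA in S154A cells were not called in S154D cells. A small rise on 1 array is not excluded. On S154D_CDCA 1 FGF19 was at -4.92, FABP6 at -4.75 and OSTalpha at 0.96, against at most -6.06, -6.00 and 0.65 on S154D_DMSO arrays. FETUB and SDC1 did not lie above those arrays. The tables argue against less transfected FXR transcript in S154D cells, since the NR1H4 log2 difference in CDCA was -0.0303 with a 95% interval from -0.36 to 0.30, which says nothing of the protein. For the 5 targets raised in S154A cells they also argue against a constant shift between slides as the whole cause: with slide as a block, the difference between the responses had a median of -2.5618, and for OSTalpha, FETUB and SDC1, well above background on all 12 arrays, the upper 95% bounds were -1.78, -0.88 and -0.77, though none was called over all genes (adjusted p = 0.297). These 5 were selected for their rise on the same S154A arrays, which makes the difference more negative. Over all 24 FXR targets tested its median was -0.09 without the block, and its mean was -0.70 with it. S154D_CDCA arrays that were labelled wrongly, or cells that were not given CDCA, cannot be told apart from a lost response, since no list that CDCA shifts without FXR is known here and the stress response list, at a mean of 0.24 in S154A cells, had 0.0264 in S154D cells. The 0.24 rests on S154A_DMSO arrays, above which this list also lay in S154D_DMSO (mean 0.17). A weaker activation of FXR S154D by CDCA may be the cause and stays open, as does a difference at the protein level, which arrays do not measure.

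CDCA was followed by many small changes in S154D cells, which tracked the GC content of the probes. After the correction for probe GC 0 genes were called by limma and 3786 had an unadjusted p under 0.05, and the median absolute log2 change of the 2073 genes went from 0.62 to 0.38 at nearly the same standard error. Among large changes SENP6 (1.43 to 0.67), ZNF509 (1.63 to 0.75) and WWC2 (1.87 to 1.16) shrank, while ALDH3A1 (2.97 to 3.04, adjusted p = 0.141) and HFE (-1.78 to -2.08, 0.141) did not shrink and still lost their call. The size is uncertain for both: no S154D_DMSO array was well above background for ALDH3A1, and HFE had -1.55 and -0.57 on its other probes before the correction. An adjusted p also depends on how many genes have a small p, here 3786 against 6102 before. Probe GC content may therefore account for part of the pattern; a response of the cells that happens to follow GC stays open. Slide differences alone are argued against by the correlation across genes, which are not independent replicates, of 0.5238 between the response within slide 3 and that of the other 4 S154D arrays, and 0.42 after the GC correction.

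For CDCA in S154A cells 1 of 10 splits of the 6 arrays gave as many genes, the real one with 27, and the highest other split gave 0 by limma. For CDCA in S154D cells it was 1 of 10, with 2073 genes and 0 in the highest other, for S154D against S154A in DMSO 10 of 10, with 0 and 0, and for S154D against S154A in CDCA 1 of 10, with 82 and 2. These 10 splits are too few for a share under 0.05.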

How the results depend on the processing

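The correction for probe GC, the fits without slide 2 or slide 4 and the block on array position were chosen after seeing the data. Under every alternative run, the FXR target list stayed called for CDCA in S154A cells (mean 0.30 to 0.89) by camera at the preset correlation, though not with an estimated one (adjusted p = 0.174), and not called for CDCA in S154D cells or for S154D against S154A in DMSO, and NR1H4 was called in no comparison. Counts of 0 are by limma, and the causes of the changes below were not tested unless one is given.

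Quantile normalisation gave 196 genes for S154D against S154A in CDCA and 118 for the difference between the responses, and normexp gave 197 and 197; 78 of the 82 and 28 of the 30 genes were still called with the former. Both turned the mean of the ribosomal list in DMSO to -0.0117 and -0.0199, and quantile normalisation put RPS2 with CDCA in S154D cells at 0. On the series table, which lacks scaling between arrays, the counts were 15 for CDCA in S154A cells, 1 for CDCA in S154D cells, 1 for the mutants in DMSO, 9 for the mutants in CDCA and 2 for the difference between the responses. There the median of all genes moved to -0.14, 0.18, -0.24, 0.10 and 0.32 in that order, and 60% of the genes called in S154A cells were higher.

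Without the filter on dim probes, which tests more genes, 0 genes were called for CDCA in S154D cells (5700 at an unadjusted p under 0.05), 31 for the mutants in CDCA and 0 for the difference between the responses (4181). With only probes well above background on all 12 arrays, 147 were called for the mutants in CDCA and 116 for the difference between the responses. The mean of a gene's probes moved no count past 1.5 times, and OAS3 with CDCA in S154D cells turned to -0.0425.

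With slide as a fixed block the counts were 7 for CDCA in S154A cells, 0 for CDCA in S154D cells (4508), 3 for the mutants in CDCA and 0 for the difference between the responses (3065). With slide as a random block the difference between the responses gave 15. With replicate number as a block the counts were 0 for CDCA in S154D cells (6116), 53 for the mutants in CDCA and 6 for the difference between the responses; nothing in the labels pairs the arrays, and same-numbered arrays did not all deviate together (correlations from -0.35 to 0.51, 9 of 18 above 0.1), although 6 of 12 lay closest to an array of their own number. A variance trend with robust moderation gave 164 for the mutants in CDCA and 111 for the difference between the responses. A minimum of 1.5-fold left 1193 for CDCA in S154D cells, by its own construction. Only the 6 arrays compared, which leaves fewer degrees of freedom, gave 12 for CDCA in S154A cells, 0 for CDCA in S154D cells (5246) and 14 for the mutants in CDCA.

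The GC correction gave 0 genes for CDCA in S154D cells (3786), 51 for the mutants in CDCA and 14 for the difference between the responses, and FBXO5, HMG4L and NCBP1 were no longer called there (adjusted p = 0.11, 0.0517 and 0.193). Without slide 2 the counts were 9 for CDCA in S154A cells, 6 for CDCA in S154D cells, 18 for the mutants in CDCA and 6 for the difference between the responses. Without slide 4 they were 14 for CDCA in S154A cells, 51 for the mutants in CDCA and 0 for the difference between the responses (5558). With array position as a block 0 were called for CDCA in S154D cells (4558) and 0 for the mutants in CDCA (3120). The correlation of both responses across genes was -0.181 with the GC correction, -0.0043 without slide 2 and -0.224 without slide 4.

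The FXR target list passed for the difference between the responses with quantile normalisation (mean -0.7834), normexp (-0.5559), the series table (-0.4456), no filter (-0.7284) and without slide 2 (-0.8523), and also without S154A_DMSO 1, S154A_DMSO 2 or S154D_DMSO 3 (smallest adjusted p = 0.0144). These are by camera at the preset correlation; with an estimated one, run on the fit reported, it did not pass (adjusted p = 0.847). For the mutants in CDCA it no longer passed with probes well above background on all 12 arrays (-0.2493), where FGF19 and FABP6 are left out, only the 6 arrays (-0.8127), the GC correction (-0.8001) and the block on position (-0.7818).

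With each array left out in turn, the counts were 14 to 17 for CDCA in S154A cells, 0 to 2173 for CDCA in S154D cells, 0 to 0 for the mutants in DMSO, 19 to 285 for the mutants in CDCA and 0 to 67 for the difference between the responses. The mean of the FXR list was 0.6846 to 0.8947, -0.0866 to 0.1465, -0.9604 to -0.7273 for the mutants in CDCA and -0.876 to -0.6236 for the difference between the responses, and the correlation of both responses was -0.1986 to 0.0812. These fits leave 2 arrays in a group.

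Over all other values, those of called genes were 1152 times the same, 1312 times no longer called and 2 times reversed, and those of called lists 65, 33 and 2 times. Of values not called, 11321 of genes and 2357 of lists were the same, and 114 and 24 became called. The lists were not run with slide as a random block, nor array position for comparisons with S154A_DMSO. NR0B2, ABCB11 and CYP7A1 had too little signal over background to be tested.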

Other observations

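The metallothionein test was chosen only after its result had been seen. In S154A cells CDCA raised MT2A, a metal-binding protein (1.11 ± 0.12, adjusted p = 0.0069, not called with slide as a block, at 1.07 and adjusted p = 0.0685), and the 9 other metallothionein genes tested, though 0 of them were called, all lay higher, by 0.14 to 0.82 with a mean of 0.4953 (camera p = 2.87e-12, and p = 0.028 with an estimated correlation). In S154D cells their mean was 0.0855 (p = 0.652) and MT2A had 0.40 (adjusted p = 0.0646), and the difference between the responses of the 9 had a mean of -0.41 (p = 0.00104, and p = 0.244 with an estimated correlation). Metallothionein genes are near-identical in sequence, so 1 transcript may be read by several probes, which the arrays cannot tell apart from a response of the family.

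Members of the lists that were called with CDCA in S154D cells went both ways. Over all genes 2073 of 20355 were called, so a few called members do not set a list apart from the rest. Of 29 stress response genes 3 rose, DNAJB9 (0.67), ATF3 (0.51) and MTHFD2 (0.50), while 16 had a negative change and the list did not pass by camera (adjusted p = 0.919). Also higher were GCLM (0.66) and GCLC (0.58), which make glutathione, the interferon-stimulated genes IFIT2 (0.68), OAS3 (0.52) and USP18 (0.40), and ACOX2 (0.61), ACADM (0.54) and ADFP (0.34) of lipid metabolism. Among fatty acid synthesis genes ACSL3 (0.56) and ELOVL5 (0.51) rose and FASN (-0.80) fell. Of 30 nuclear receptors and coregulators 4 fell, RXRB (-0.78), NR2F6 (-0.75), NR2F2 (-0.59) and PRMT1 (-0.40), and the list did not pass by camera (adjusted p = 0.376). Also lower were ENO1 (-0.56) and GAPDH (-0.51) of glycolysis, COL1A1 (-0.56), SULT1A1 (-0.42), RPS2 (-0.48), NDUFV1 (-0.43) and CORO1A (-0.62). OAS3 turned with the mean of its probes, and RPS2 was at 0 with quantile normalisation.

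Other lists held rises and falls side by side in S154D cells: BAG3 (0.58) and HSPB8 (-0.40) of the heat shock proteins, EGR2 (0.61) and CCND1 (-0.61) of the immediate early genes, BIRC3 (0.54) and NFKB2 (-0.64) of the NF-kB genes, CCNB1 (0.62), PCNA (0.51), CDC20 (-0.54) and MCM5 (-0.44) of the cell cycle, SESN1 (0.40), BAX (-0.67) and XPC (-0.46) of the p53 targets, PSMD4 (0.55), PSMD14 (0.42) and PSMD2 (-0.87) of the proteasome, TACSTD1 (0.51), OCLN (0.51) and CLDN4 (-0.70) of the epithelial markers, and TBP (0.79), GUSB (0.62) and HPRT1 (0.50), with GAPDH, of the housekeeping genes. No hepatocyte marker was called. These calls share the dependence of the 2073 genes on probe GC, arrays and slides.

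The median or mean of a list and the direction of camera, which compares its members with all other genes, differed in sign for some lists that were not called. With CDCA in S154A cells these were fatty acid oxidation, immediate early, NF-kB, p53, proteasome, xenobiotic, extracellular matrix, ribosomal, mitochondrial and leukocyte lists, and in S154D cells the stress response. For S154D against S154A they were the FXR, p53 and epithelial lists in DMSO, and in CDCA the lists of fatty acid synthesis and oxidation, NRF2, immediate early, hypoxia and housekeeping genes. For the difference between the responses they were NF-kB, hypoxia and housekeeping genes.

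In the remaining comparisons no list beyond those named passed by camera, or by fry for a move one way on balance. The smallest camera adjusted p of these was 0.0611 for S154D against S154A in DMSO (immediate early genes), 0.295 in CDCA and 0.12 for the difference between the responses. By fry, members of many lists differed in either direction in the last 2, such as xenobiotic metabolism (adjusted p = 9.18e-06 and 8.62e-05) and housekeeping genes (0.000751 and 0.000174). In DMSO none did (smallest adjusted p = 0.29). Since fry does not set a list against the other genes, these results do not single out the lists named. By limma 4802 and 4560 of all 20355 genes had an unadjusted p under 0.05 in those comparisons, against 884 in DMSO.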
